A study of Curcuma longa with 2 samples.

How the data were processed

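Small RNA of turmeric nanoparticles was measured in 2 libraries of 1 group. Per the labels' protocols, total RNA was taken up with a column kit for small RNA (miRNeasy), libraries were made with the Illumina TruSeq small RNA chemistry, pooled in equal amounts and sequenced on an Illumina HiSeq instrument. The submitters' processing notes name CASAVA 1.8.4 and cutadapt 1.10 without their role. Per the file headers, reads were matched to miRNAs and hairpins of miRBase for selected plant species, hairpins were placed on a genome and expressed sequences, and sequences without a match were predicted from genomic hairpins by structure criteria. The miRBase release, the aligner, the species selected and the genome assembly are not given in the sources used here.

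The deposited table gives, per listed locus, an expected count of reads for each library, which per the file headers is the raw number of reads. It also gives a normalized signal that the authors made from it. By the values, that signal is the raw column times 1 constant factor per library, 0.508 and 0.923, so shares are identical on both scales, and the method behind the factors is not given in the sources used here. A hairpin free energy index, per the file headers computed by the authors from free energy, length and GC percent, was used as another value in 2 closing tests. The sheet held 278 lines below its header, of which 12 hold no entry here and are not analysed here, so that totals, shares and statements of no reads cover the remaining entries only, leaving 266 lines and 186 distinct sequences. Of these, 19 were at 0 in both libraries and were left out. The table also has 2 value columns that match no sample of this series, and they entered no step.

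A sequence could stand on up to 2 lines, and 73 of those with reads did. The value set down before the data were examined counted each distinct sequence once. After the data were examined, this was carried out as the sum over a sequence's lines, because the reads of a sequence appear to be divided over its loci. Its lines carry equal values. Of the sequences on 2 lines, 29 of 71 in library 1 and 38 of 70 in library 2 had a fractional value on a single line, against 0 and 1 after summing (tolerance 1e-06). The summed columns gave whole totals, 96386 and 72196, where single lines gave 64396.5 and 49275.7. For 4 of 4 predicted sequences on 2 lines, the number in the name exceeded the reads of a single line over both libraries, and for 0 of 15 on 1 line. It never exceeded the summed lines, but equalled them for only 1 of these 4, and for 8 of 15 on 1 line, so it does not settle the count. As a further limit, 24 of 87 sequences on 1 line in library 1 were fractional too, so the division is not fully resolved. Some of these are near-identical sequences with equal values. For example, 2 miR396 forms that differ in the last base each had 38.5 reads in library 1 and 25.5 in library 2. Distinct sequences may therefore share reads. For shares, the sum equals the alternative planned as every line counted, except for 1 sequence named for both miR319 and miR159. The literal reading, a single line's value, became the alternative, and it leaves the order of the leading families miR319 and miR2916 open and turns 6 other pairs. The header describes each listed sequence as the best-scoring read of a cluster, so a value may include reads of near-identical forms.

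Families follow the number after miR or MIR in the first name, with miR156 and miR157, miR165 and miR166, miR170 and miR171, and miR482 and miR2118 merged. The class of a sequence (exact, end change, substitution, unregistered arm) also follows its first name. Entries are called loosely matched where every name is on an unregistered arm or has 2 substitutions and no registered sequence quoted in the table is identical. Shares are percent of the listed reads of a library, given as mean ± SD (n = 2) with exact Clopper-Pearson 95% intervals where a single library is described. Intervals cover counting error only, since reads without molecular identifiers are not independent molecules. No upper limit is given for values of 0, because the smallest value above 0 was 2.5 reads and the list may have a minimum. The 8 lists by function or lineage, the alternatives and the rule for names were fixed before the data were examined. The rule takes the 15 families and 10 sequences with the highest mean share, the leading 3 families of each list, and the 5 sequences with the largest ratio in each direction among the top 25% by mean. Other families in the text (miR167, miR172, miR393 and miR160, and families without reads) were chosen after their values were seen.

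Libraries were compared by Pearson's r on log2(reads + 1) and Spearman's rho across sequences, by a chi-square test over sequences with at least 10 reads in total, and by a two-sided exact binomial test per sequence with Benjamini-Hochberg adjustment at 0.05. Fractional values were rounded to whole reads for these tests, and ratios add 0.5 to each count. Tested on simulated data for the comparison of library 2 with library 1 (all sequences with reads, 50 runs), the binomial test recovered 80.8% of 40 sequences changed 4-fold, with 1.12 false calls per run. The simulation drew Poisson counting noise only, while the libraries differ by more than that, so the false calls between them may be more frequent. Alternatives changed the counting of repeated sequences, filters, the pseudocount, the denominator, the value column and the sequences left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Hairpin positions are not printed, because the assembly is not named and its contigs carry only database identifiers. The gene table supplied for another assembly of the species was not used here.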

Results

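Small RNA of nanoparticles from turmeric (Curcuma longa) root was sequenced in 2 samples, called library 1 and library 2 here. They form 1 group with no control or second condition, so the values describe which plant miRNAs were listed for these samples. RNA held by the particles cannot be told apart from RNA isolated with them. The deposited table listed 96386 reads in library 1 and 72196 in library 2 over the entries used here. These are totals of a list of miRNA entries, not the sequencing depth, which is not given in the sources used here. Nothing in the labels says that the samples came from separate preparations, so the spread between them may be technical.

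Of the distinct sequences with reads, 153 had reads in both libraries, 5 in library 1 alone and 9 in library 2 alone. These sequences carried the names of 43 registered miRNA families, 41 of them with reads in both libraries, or had no registered name. A name is not always a close match: 51 sequences, with 29.2% ± 0.36 (SD, n = 2) of the reads, were loosely matched as defined above. For some families, among them miR5368, miR395 and miR2592, all reads lay on such entries. No sequence found in 1 library alone had more than 57 reads. The 10 most abundant sequences together held 71.6% of the reads in library 1 and 70.8% in library 2. The smallest value above 0 was 2.5 reads, so a sequence listed at 0 may lie under a minimum used for the list. Shares below are percent of listed reads, as mean ± SD over the 2 libraries.

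The first question was which families made up the miRNA content. miR319, whose known targets are TCP transcription factor genes, held the largest share at 27.6% ± 1.38 (SD, n = 2). The related miR159 family, which targets GAMYB-type MYB genes, held 14.5% ± 0.061 (SD, n = 2). Both families together accounted for 42.0% ± 1.31 (SD, n = 2) of the reads through 19 sequences. Between them ranked miR2916, a registered entry proposed to be a fragment of ribosomal RNA, at 17.8% ± 0.14 (SD, n = 2). miR535 followed at 9.74% ± 0.072 and miR156/miR157, which targets SPL transcription factor genes, at 7.77% ± 0.24 (SD, n = 2 each).

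The miR165/miR166 family, known to target class III homeodomain-leucine zipper genes, held 4.71% ± 0.0058 (SD, n = 2). miR396, which targets growth-regulating factor genes, held 2.50% ± 0.11, and miR162, which targets the Dicer gene DCL1, held 1.73% ± 0.23 (SD, n = 2 each). miR528 reached 1.05% ± 0.011 and was the last of 9 families at or above 1%. Lower still were miR170/miR171 at 0.89% ± 0.030, miR168 at 0.82% ± 0.022 and miR164 at 0.65% ± 0.021 (SD, n = 2 each). miR169 stood at 0.63% ± 0.046, miR5179 at 0.59% ± 0.025 and miR482/miR2118 at 0.44% ± 0.021 (SD, n = 2 each). The 3 leading families summed to 59.8% ± 1.17 and the leading 15 to 91.3% ± 0.53 of the reads, and 16 families lay under 0.1%.

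One family was placed above another only where it was higher in both libraries and the mean log2 ratio exceeded its SD. By this rule 104 of the 105 pairs among the 15 leading families were ordered, as were 13 of the 14 pairs of neighbouring ranks. miR319 exceeded miR2916 by 1.55-fold, and miR2916 exceeded miR159 by 1.23-fold. The exception was miR164 against miR169, at 1.02-fold. The order of miR2916 and miR159 rests on 1 sequence named for both miR319 and miR159, at 4.22% ± 0.094 (SD, n = 2). It is counted under miR319, its first name, with 2 substitutions, while its miR159 name has 1. Split over both names, miR319 held 25.5% and miR159 16.6%, against 17.8% for miR2916. Counted wholly under miR159, it would place that family above miR2916 in both libraries. No p-value was attached, since ratios within 2 libraries cannot give a two-sided exact sign-flip permutation p below 0.5. Counting error alone gave miR319 a 95% Clopper-Pearson interval of 28.3% to 28.8% in library 1 and 26.3% to 26.9% in library 2.

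The place of miR319 at the top depends on how sequences listed at more than 1 locus are counted. Summed over loci, as here, miR319 led in both libraries. With the value of a single locus miR319 and miR2916 were not ordered, at 22.5% and 22.3% in library 1 and 20.6% and 22.6% in library 2. Of the 104 ordered pairs, 96 kept their order with single-locus values, 2 were not ordered and 6 turned. The turned pairs placed miR156/miR157 above miR535, miR528 above miR162, miR164 above miR170/miR171 and miR168, and miR482/miR2118 above miR169 and miR5179. The miR159 share rests on 1 sequence, and without it the family held 0.87% of the remaining reads. That sequence carries 2 substitutions, and without entries that every listed name places on an unregistered arm or gives 2 substitutions, here called loosely matched, miR159 held 0.91% and miR2916 7.40%. The 0.91% leaves the sequence named for both miR319 and miR159 under miR319, although only its miR159 name passes this filter.

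**Figure D1:**
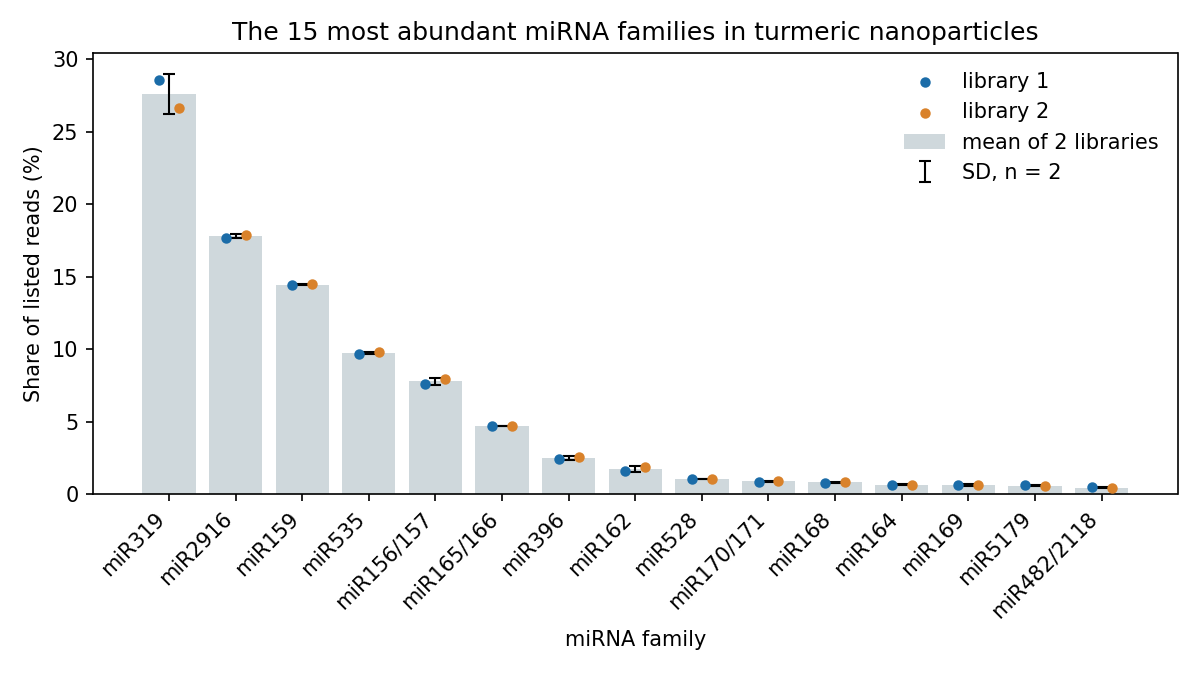
Share of listed reads (%, vertical axis) of the 15 most abundant miRNA families; bars are means of the 2 libraries, error bars the SD (n = 2), and points the single libraries. miR319 at 27.6%, miR2916 at 17.8% and miR159 at 14.5% stand above the rest, and the points of each family lie close together.

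Single sequences showed the same concentration. The most abundant was the miR159 sequence TTTGGATTGAAGGGAGCTCCC, at 13.7% ± 0.052 (SD, n = 2), listed under rice miR159 names with 2 substitutions. The miR319 sequences TTGGACTGAAGGGAGCTCCC and TTGGACTGAAGGGAGCTCCTT held 11.3% ± 0.97 and 6.12% ± 0.19 (SD, n = 2 each). The miR535 sequence TGACAACGAGAGAGAGCACGC, identical to its registered rice form, held 8.65% ± 0.31 (SD, n = 2). Also among the leading 10 were 3 sequences of miR2916, GCCGACCAGGGATCGGTGGATGTT at 7.08% ± 0.27, ATACCGTCCTAGTCTCAACCATA at 5.43% ± 0.33 and TGGGGGCTCGAAGACGATCA at 5.24% ± 0.46 (SD, n = 2 each). The miR156/miR157 sequence TTGACAGAAGAGAGTGAGCAC held 4.44% ± 0.12 and the miR165/miR166 sequence TCGGACCAGGCTTCATTCCCC 4.41% ± 0.00085 (SD, n = 2 each). The remaining member of the leading 10, CTTCCAATTCCTCCCATTCCGA, had no registered name and held 4.80% ± 0.66 (SD, n = 2). It contains the leading miR482/miR2118 sequence, and with it that family would hold 5.24% in place of 0.44%.

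The families were next grouped into lists by known function or lineage. Families that act mainly on regulators of development held 60.2% ± 1.05 (SD, n = 2) of the reads, with 13 of 14 listed families present in 73 sequences. miR319, miR159 and miR156/miR157 led this list. Its lower members included miR167 at 0.34% ± 0.0049, which targets auxin response factor genes, and miR172 at 0.18% ± 0.014, which targets AP2-type genes (SD, n = 2 each). miR393, which targets auxin receptor genes, held 0.071% in both libraries. miR160 stood at 0.20% ± 0.039 (SD, n = 2), but 87.6% of its reads in library 1 and 94.3% in library 2 lay on loosely matched entries. miR390, which acts on TAS3 transcripts, had no reads in the entries used here.

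Families that act on the silencing machinery held 2.54% ± 0.25 (SD, n = 2). Of the 3 listed, miR162 and miR168, the latter a regulator of AGO1, had reads, and miR403 had none. The disease-resistance list had reads for 1 of its 4 families, miR482/miR2118, which targets NBS-LRR resistance genes.

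The nutrient and copper list held 1.22% ± 0.026 (SD, n = 2), with 3 of 9 families present. miR528, which targets genes of copper-containing proteins in grasses, made up most of it. miR395, which targets sulfate assimilation genes, held 0.17% ± 0.010 (SD, n = 2), all of it on loosely matched entries. These are 18 or 19 nt long and overlap one another and the sequences named miR6105, so the presence of miR395 rests on the name. miR399, which acts in phosphate homeostasis, had 5 reads in library 2 and was listed at 0 in library 1. miR397, miR398 and miR408, which target laccase and other copper protein genes, had no reads in the entries used here.

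The monocot-associated list held 1.11% ± 0.0091 (SD, n = 2), with 3 of 4 families present. These were miR528, miR1432 at 0.031% ± 0.0037 and miR444, which targets MADS-box genes, at 0.029% ± 0.0058 (SD, n = 2 each). All reads of miR1432 and miR444 lay on loosely matched entries. None of the 5 eudicot-associated families had reads. The first names of the sequences used 23 species prefixes, and none of the 18 animal prefixes looked for was among them. The legend of the table speaks of selected species without naming them, so the missing animal names set no limit on animal miRNAs.

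Entries that have been proposed to be rRNA or tRNA fragments held 18.6% ± 0.12 (SD, n = 2), with 7 of 15 families present in 28 sequences. miR2916 made up nearly all of this share, followed by miR5368 at 0.41% ± 0.038 and miR6478 at 0.16% ± 0.0099 (SD, n = 2 each). Without loosely matched entries the list held 7.88%.

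Names of registered miRNAs covered 94.4% ± 0.78 (SD, n = 2) of the reads and 148 of the sequences. The 19 predicted sequences held the remaining 5.63% ± 0.78 (SD, n = 2), most of it on the 1 sequence that extends miR482/miR2118. Of the sequences with registered names, 51 were loosely matched and held 29.2% ± 0.36 (SD, n = 2) of the reads. By the first name listed, 18 sequences were identical to a registered mature form and held 21.9% ± 0.18 (SD, n = 2), among them the leading forms of miR535, miR165/miR166 and miR528. By any name, or any registered sequence quoted in the table, 30 sequences were, with 25.2% ± 0.10 (SD, n = 2), the leading miR168 sequence among them. The other classes also follow the first name. Forms with 1 or 2 substitutions held 37.1% ± 0.12, a class led by the miR159 sequence (SD, n = 2). Forms longer or shorter at an end, led by miR319, held 19.5% ± 1.14 (SD, n = 2). Unregistered arms of registered hairpins, led by miR2916, held 15.9% ± 0.42 (SD, n = 2). The names are mostly those of other plants, so a substitution here is a difference from another species' entry.

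Sequences of 21 nt held 58.6% ± 0.71 (SD, n = 2) of the reads and 50.3% of the sequences. Those of 20 nt held 21.5% ± 1.87, mainly through miR319, and those of 22 nt 5.38% ± 0.65 (SD, n = 2 each). Lengths of 24 nt at 7.14% ± 0.27 and 23 nt at 5.71% ± 0.38 came mainly from miR2916 (SD, n = 2 each). U was the first base of 76.9% ± 1.19 of the reads, against 9.35% ± 0.72 for C, 7.62% ± 0.23 for G and 6.17% ± 0.24 for A (SD, n = 2 each). In the development list, 95.2% ± 0.18 of the reads were 20 to 22 nt long with a first U, against 29.2% ± 2.55 in the fragment list (SD, n = 2 each).

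**Figure D2:**
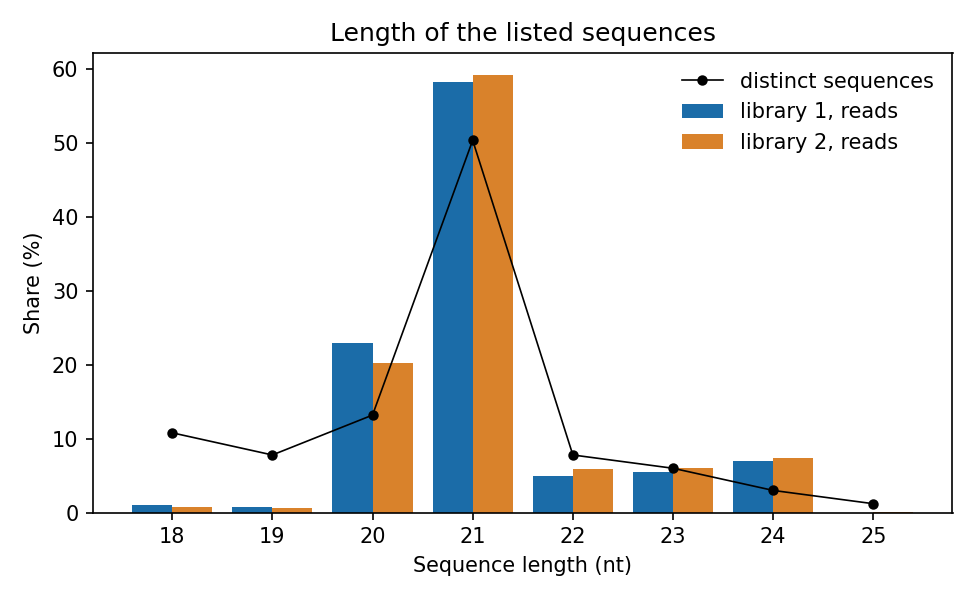
Share (%, vertical axis) of listed reads per sequence length (nt, horizontal axis) in library 1 and library 2 as bars, with the share of distinct sequences as a line. The 21 nt class holds 58.1% of the reads in library 1 and 59.1% in library 2.

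The last question was how far the 2 libraries differ. miR319 held 28.6% in library 1 and 26.6% in library 2, with intervals that do not overlap, and miR162 held 1.56% and 1.89%. miR159, at 14.4% and 14.5%, and miR165/miR166, at 4.72% and 4.71%, were closer. Across the sequences, which are not independent replicates, Pearson's r of log2(reads + 1) was 0.919 and Spearman's rho 0.934. Of the 153 sequences with at least 10 reads in total, 140 differed by less than 2-fold in share, and the median difference was 1.16-fold. The libraries still differed by more than counting noise, with a chi-square of 1164.54 on 152 degrees of freedom (p = 1.49e-155). Without the miR535 forms that carry A9C, described next, the chi-square fell from 7.66 to 3.72 per degree of freedom. An exact binomial test with Benjamini-Hochberg adjustment called 23 sequences at 0.05, 13 of them higher in library 2 and 10 higher in library 1. Of these, 8 were listed at 0 in 1 library, and 2 of the other 15 differed by 2-fold or more. Without adjustment, 40 sequences had a p below 0.05.

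Among the top 25% of sequences by mean share, the miR535 form TGACAACGCGAGAGAGCACGC stood apart. It carries A9C relative to the registered form, counted from 1 at the 5′ end, and had 24 reads in library 1 and 452 in library 2, a 24.7-fold difference in share (exact binomial test, adjusted p = 1.47e-130). The next largest log2 ratios were 0.38 for the unnamed CGCGTGCGCGGCCCCTGCC and 0.36 for the miR170/miR171 sequence CGATTGAGCCGTGCCAATATC, neither past the threshold (adjusted p = 0.193 and 0.156, exact). CTTCCAATTCCTCCCATTCCGA and the leading miR162 sequence TCGATAAACCTCTGCATCCGG were 1.21-fold higher in library 2 and passed it (adjusted p = 2.85e-16 and 1.13e-05, exact). In the other direction, the miR2592 sequence ATTCCCACTGTCCCTGTCT was 1.84-fold higher in library 1 (adjusted p = 0.000140, exact). The miR319 sequence TTGGACTGAAGGGAGCTCCT was 1.19-fold higher there (adjusted p = 3.70e-07, exact). Sequences of miR160, miR394 and miR164 had ratios of 1.22, 1.17 and 1.17 and did not pass the test. These tests compare the 2 libraries by their reads and say nothing of other preparations.

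**Figure D3:**
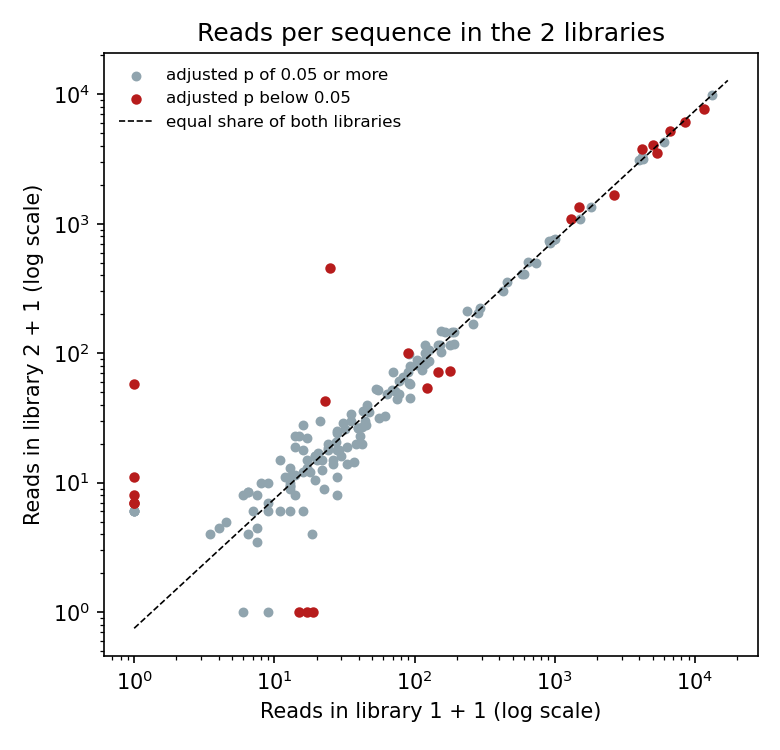
Reads + 1 per sequence in library 1 (horizontal axis) and library 2 (vertical axis), both on log scales; red points have an adjusted p below 0.05 in the exact binomial test and the dashed line marks equal shares. Most sequences lie near the line, and the A9C form of miR535, at 24 and 452 reads, lies far above it.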

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

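The alternatives on loosely matched entries (an unregistered arm or 2 substitutions) and on exact forms by any name, those with predicted sequences moved to the family they extend, without the A9C forms of miR535, with at least 10 reads summed, and for length and first base without the fragment list were chosen after seeing the data, as was the sum over loci used throughout. With a single locus value per sequence, the literal reading of the plan, miR319 held 21.6%, the development list 54.8%, the fragment list 23.2%, registered names 91.8%, 21 nt 55.4%, a first U 67.3% and exact forms 21.5%, and 13 sequences differed between the libraries. Among registered names only, miR319 held 29.2%, the development list 63.8% and the fragment list 19.7%. miR319 held 25.5% with values split over families named, 33.9% without the fragment list and 32.0% without the most abundant sequence. Without entries loosely matched by every name it held 38.9%, the development list 64.9% and the fragment list 7.88%, while miR159 fell to 0.91%. Judged by the first name alone, which also drops the leading miR162 and miR168 sequences though other names or registered sequences match them more closely, these were 35.5%, 64.4%, 8.84% and 1.03%. In the setting by every name, the miR319 and miR159 values depend on 1 sequence named for both, at 4.22% of all reads. Only its miR159 name, with 1 substitution, passes that filter, but its reads stay under miR319. Counted under miR159, they would lower the miR319 value and raise that of miR159. Exact forms by any name or quoted registered sequence held 25.2%. Without the fragment list, 21 nt held 71.6% and a first U 87.6%. Pearson's r was 0.975 with at least 10 reads in both libraries, 0.891 and 0.972 with pseudocounts 0.5 and 10, and 0.976 for sequences above 0 in both. With at least 10 reads in both, and for sequences above 0 in both, 14 sequences differed. Smaller denominators and fewer sequences follow from how these settings are built, and for the rest the cause was not tested. Single libraries gave ranges of 26.6% to 28.6% for miR319 and 59.5% to 61.0% for the development list. With 2 libraries, a single value lies within 1 SD of the mean by construction, so this says nothing of stability. The normalized column changes no share. No paired analysis was possible because there is 1 group, so no groups could be paired; families were compared within each library. The unknown library depth limits any statement on absolute amounts.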

Other observations

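All tests in this part were chosen after the results were seen, and those of the base-call error and of the hairpin index were revised after their values were known.

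Some families were represented by both arms of a hairpin. In 21 pairs of arms with reads, outside the fragment list and without the A9C form of miR535 and 3 pairs that share a run of 8 nt or more, the more abundant arm was the 5′ arm in 11 and the 3′ arm in 10. The ratio of arms could be taken in both libraries for 18 pairs, with a median of 7.08. It was 10 or more in 8 pairs by the mean, in 8 in library 1 and in 9 in library 2. Some pairs join arms named for different families, such as miR482/miR2118 with miR2592, miR5652 with miR7771 and miR319 with miR159. Several arms also recur across pairs, so the counts and the median are not over independent miRNA hairpins. The leading miR159 sequence exceeded the other sequence listed in its hairpin 611-fold (geometric mean of 2 libraries, values per locus). Whether these 2 sequences pair was not tested. A sequence named for the 5′ arm of miR159a, listed in another hairpin, had 88 reads in library 1 and 99 in library 2. Against that sequence the ratio would be lower. On the same scale, miR156b exceeded its opposite arm 189-fold, miR162 72.7-fold, miR168 18.3-fold and miR528 16.8-fold. The opposite arm of miR528, CCTGTGCCTGCCCTTTCCACT, was listed as a predicted sequence with 52 reads in each library. Ratios use the form listed at each locus, which can be a trimmed one, and those of sequences on 2 loci assume that both arms are divided alike. Base pairing was not tested for the other pairs either, so the counts and the median hold for arms as listed.

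Of the 28 sequences in the fragment list, which holds 18.6% of the reads, 15 (53.6%) overlapped another listed sequence by at least 10 nt at a start shifted by at least 3 nt, against 1 of 73 (1.37%) in the development list (two-sided Fisher's exact test, p = 1.73e-09). This test, like the permutation test below, treats sequences as independent, although both partners of an overlap are counted and families hold related sequences. The p-values are therefore too small. miR2916, with 5 of the 28 sequences, holds nearly all reads of the list, while miR6300 has 8 sequences with 0.13%. Development entries are mostly listed as forms of a registered mature sequence, which leaves less room for shifted starts. Pieces of longer abundant RNAs are a candidate explanation, although no reference of turmeric rRNA was used here and the source of these entries stays open. The median hairpin free energy index was 0.55 against 0.9 in the development list (two-sided permutation test with 100000 resamples, p = 0.00174). However, miR159 and miR319, which hold most development reads, had a median of 0.5 (permutation p = 0.816 against the fragment list) and miR2916 0.5. The index cannot decide here, because some hairpins listed for miR319 are too short to hold both arms. Over the miR319 sequences it ranged from 0.4 to 1.2. Whether the fragment entries come from hairpins like those of the development list therefore stays open. A sequence named miR168, CGGTGGATGTTGCTCTTA, with 42 and 35 reads, also lay in a miR2916 hairpin, and no biological explanation was tested.

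In the main difference between the libraries, the A9C form of TGACAACGAGAGAGAGCACGC made up 24 reads (0.28%) in library 1 and 452 (6.92%) in library 2, and that of CGACAACGAGAGAGAGCACGT 0 reads and 57 (10.3%). A variant at 1 locus in the material of library 2 would leave the other form at 0 reads with the change, and the 57 reads argue against that. The shares of both forms in library 2 differed beyond counting error (two-sided Fisher's exact test, p = 0.00594), which covers counting error only, and the listed hairpins carry the A in 6 and 1 cases and the C in 0. Another 6 sequences of miR319 and miR156/miR157 with A at position 9 and at least 1000 reads in library 2 would give 1440 changed reads at the ratio of the main miR535 form, and 0 of their A9C forms are listed. This decides nothing on a base-call error at read position 9. The table lists selected reads, a value may include reads of near-identical forms, and a missing entry excludes nothing. The error therefore stays open, as does a difference in the material of the samples. The latter was not tested, since no genome of these samples was used here.

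The most abundant sequence without a registered name, CTTCCAATTCCTCCCATTCCGA, contained 1 registered-name miR482 sequence that lay in the same hairpin. It may therefore be a longer form of that sequence, at 22 nt, and counting it there would raise miR482/miR2118 from 0.44% to 5.24%. This form was the more abundant, with 4176 reads in library 1 and 3800 in library 2. The named sequence had 293.5 and 222.5. The alternative that it arises on its own was not tested.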
